A study of Mus musculus with 3 samples.

How the data were processed

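Single-cell RNA-seq was measured in 3 libraries of CD45+ tumour leukocytes from mice with B16-cEGFR tumours, sorted by CD3 on a FACSMelody instrument, prepared with the 10x Genomics 5′ kit and sequenced on a NovaSeq instrument, per the labels. The values were UMI counts per gene and barcode as deposited, in filtered matrices that the submitters' processing notes credit to Cell Ranger 7.1.0 with build mm10; the annotation release and the intron setting were not stated. Per the labels, treated mice received 5 µg CmAb-IL2 and 80 µg CmAb-(IL10)2 on days 9 and 12, and 6 mice made up each group; whether cells of those mice were pooled was not stated. The control is called untreated in its title, and the protocol lists PBS. The matrices held 33696 features, of which 31961 were in GENCODE M21, the source of gene positions. The 26 duplicated symbols were kept apart by Ensembl identifier. The gamma-delta T cell markers Cd163l1, Tcrg-C1 and Tcrg-C2 had no feature and were not used here.

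Every deposited barcode had at least 500 UMIs. Median UMIs per barcode were 3572, 5038.5 and 4446 in the CD3− control, CD3− treated and CD3+ treated library. Cells with at least 200 detected genes and at most 10% mitochondrial UMIs were kept, which removed 3 barcodes of the control by genes, and 316, 185 and 240 barcodes by mitochondrial share. Doublets were scored with Scrublet in Scanpy 1.11.5 at an expected rate of 8%. Its own threshold was used for the CD3− treated library (9.668% removed). In the other libraries that threshold marked fewer than 0.5% of cells, so by the rule set beforehand scores above the value that bounds the top 8% were called doublets. Cells tied at that value were kept, so 7.973% (control) and 7.395% (CD3+) were called, and 1046, 1323 and 837 cells were removed in all.

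Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes, without TCR, immunoglobulin, ribosomal protein, mitochondrial, haemoglobin, sex-linked and predicted genes and Cmss1, gave 30 principal components (values clipped at 10). The libraries were clustered together without integration on a shared-neighbour graph of 15 neighbours with leidenalg 0.10.2 at resolution 1.0 and seed 1. Cells were named by cluster from fixed marker lists. A cluster took the class with the highest mean marker score if that score was at least 0.25 and 3 markers had a UMI in at least 5% of cells, unless another class scored at least 0.75 of it or led the top genes. The score had 3 versions. The earliest used CPM and was replaced after it gave cluster 19 an erythroid name. The second, used here, takes the share of cells with a UMI. The last raised the limit for the rival class to 0.8 after cluster 8 was seen to stay unnamed, and was withdrawn; the earliest and last versions are given as alternatives.

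The groups were compared without tests, because each had 1 library and cells are not replicates. Shares have exact Clopper-Pearson 95% intervals, and ratios of shares have approximate intervals from the normal distribution on the log scale. UMIs were summed per library and class, for classes with at least 100 cells in both libraries, and CPM of the sums have exact Poisson intervals; log2 ratios have exact conditional binomial intervals. All cover counting error only. A gene with 0 UMIs was set to 3 counts for a bound on its ratio. Genes named had at least 50 UMIs over both libraries together and at least 20 CPM in 1 of them, were not mitochondrial, ribosomal protein, haemoglobin, antigen receptor, sex-linked or predicted genes, and ranked among the 12 highest and 12 lowest (phagocyte-like cells) or 5 and 5 (other classes) by the interval bound nearest 0; list members and receptors were named as well.

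The gene lists, 19 in all, were fixed before the files were read: type I interferon, interferon-γ, MHC class I, MHC class II, IL-10/STAT3, IL-2/STAT5, cytotoxicity, proliferation, inflammatory cytokines, chemokines, tumour-associated macrophage genes, DC maturation, hypoxia, oxidative phosphorylation, dissociation stress, complement, T cell checkpoints, progenitor or memory T cells, and the receptors. Another 5 held markers of T cells, melanoma, fibroblasts, endothelium and erythroid cells. A list needed 3 members with at least 20 UMIs, members were counted as higher or lower at 1.5-fold, and the median was placed among 10000 random lists matched in 20 bins of mean CPM. The percentile describes the list and is not a test. Shares of cells with a UMI were also taken after thinning each cell to 1000 UMIs, leaving out shallower cells.

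Ratios were checked on simulated Poisson counts drawn from the pooled profile of both CD3− libraries at their depths. For phagocyte-like cells (11083 genes), 100.0% of 100 genes set 2-fold apart had an interval on the right side of 0, with a median error of 0.059 log2 units, and 95.6% of unchanged genes were covered by the interval. For NK-like cells (9780 genes) the values were 94.0%, 0.116 and 95.8%. Alternatives tried were other gene and mitochondrial filters, no doublet removal, other resolutions, clustering on marker genes or per library, TMM scaling (edgeR 4.0.16 in R 4.3.3), per-cell means, centring on the median gene, no minimum count and other thinning depths. Alternatives added after the data were seen were the naming versions, shares without T-like cells, phagocyte-like cells without T cell marker UMIs, comparisons within clusters, and the contrast of T-like cells between the sorts. B-like and basophil-like cells were not compared for expression, having fewer than 100 cells in the treated library. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.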

Results

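The data were 3 single-cell RNA-seq libraries of CD45+ leukocytes sorted from B16-cEGFR tumours grown in C57BL/6J mice. B16 is a mouse melanoma line, and cEGFR is the antigen name given in its label. One library held CD3− cells of control mice, 1 held CD3− cells of mice given both CmAb-(IL10)2 and CmAb-IL2, and 1 held CD3+ cells of mice given both proteins. The 2 injections were given on days 9 and 12, and tumours were collected on day 14 from groups of 6 mice. The deposited matrices held 13438 barcodes and 57994105 UMIs for the CD3− control library, 13870 barcodes and 88945562 UMIs for the CD3− treated library, and 11558 barcodes and 65888623 UMIs for the CD3+ treated library. After filtering, 12074, 12362 and 10481 cells remained, with medians of 3486, 4780 and 4398 UMIs per cell. With 1 library per group there is no replicate check, so every difference below is between libraries, and every interval covers counting error only.

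The first question was which leukocytes the tumour held after treatment. Mononuclear phagocyte-like cells were the main class of the CD3− control library, at 51.9% of cells (95% interval 51.0 to 52.8; 6264 cells), and made up 17.1% (16.4 to 17.8; 2113 cells) of the CD3− treated library, 3.04-fold lower (2.91 to 3.17). Dendritic cell-like (DC-like) cells were 9.98% and 2.14%, 4.67-fold lower, and B-like cells 4.94% and 0.469%, 10.5-fold lower (8.06 to 13.8). NK-like cells, the innate cytotoxic lymphocytes, were higher, at 14.97% (14.3 to 15.6) in the control and 20.2% (19.5 to 20.9) in the treated library. T-like cells took 1.95% of the control and 27.7% (27.0 to 28.5) of the treated CD3− library, 14.2-fold more (12.5 to 16.2), although both had been sorted as CD3−.

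Other classes were smaller. Neutrophil-like cells were 3.22% of either CD3− library, and their ratio of 0.999 (0.871 to 1.15) showed no difference detectable at this depth. Plasmacytoid DC-like (pDC-like) cells were 1.89% and 1.11%. Basophil-like cells were 36 of 12074 cells in the control and 0 of 12362 in the treated library, which allows a share of up to 0.0298%. Because the T-like cells take part of the total, shares were also taken over cells that were not T-like. Phagocyte-like cells were then 52.9% and 23.7%, NK-like cells 15.3% and 27.9%, DC-like cells 10.2% and 2.96%, B-like cells 5.04% and 0.649%, and neutrophil-like cells 3.29% and 4.46%, a ratio of 1.36 (1.18 to 1.56).

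Different clusters filled the same class in the 2 libraries. Control phagocyte-like cells lay mainly in cluster 1 (3371 cells, macrophage-like), cluster 5 (1879 cells, non-classical monocyte-like) and cluster 14 (999 cells, macrophage-like), and treated ones in cluster 4 (1989 cells, monocyte-like). Control NK-like cells lay mainly in cluster 9 (1335 cells), and treated ones in clusters 6 (1755 cells) and 13 (615 cells). A cluster drawn mostly from 1 library may reflect that library instead of a type. Names within the phagocyte-like class also changed with the resolution. At resolution 2.0 its largest control clusters (2013, 1437 and 1168 control cells) were monocyte-like, and a macrophage-like cluster held 891. At resolution 0.5 the largest (3826 control cells) was non-classical monocyte-like, and a macrophage-like one held 2566. Unnamed clusters held 10.9% of the control, 28.1% of the treated CD3− and 10.6% of the CD3+ library. The largest unnamed cluster was cluster 12 in the control (7.11%), and cluster 8 in the treated library (12.7%, against 0.190% in the control). Some settings moved a ratio by more than 1.5 times. The T-like ratio was 7.26 when cells were clustered on marker genes alone and 6.27 when each library was clustered on its own, and the NK-like ratio was 2.53, 2.44 and 2.17 with marker genes alone, with a lower clustering resolution, and with cluster 8 counted as NK-like.

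**Figure D1:**
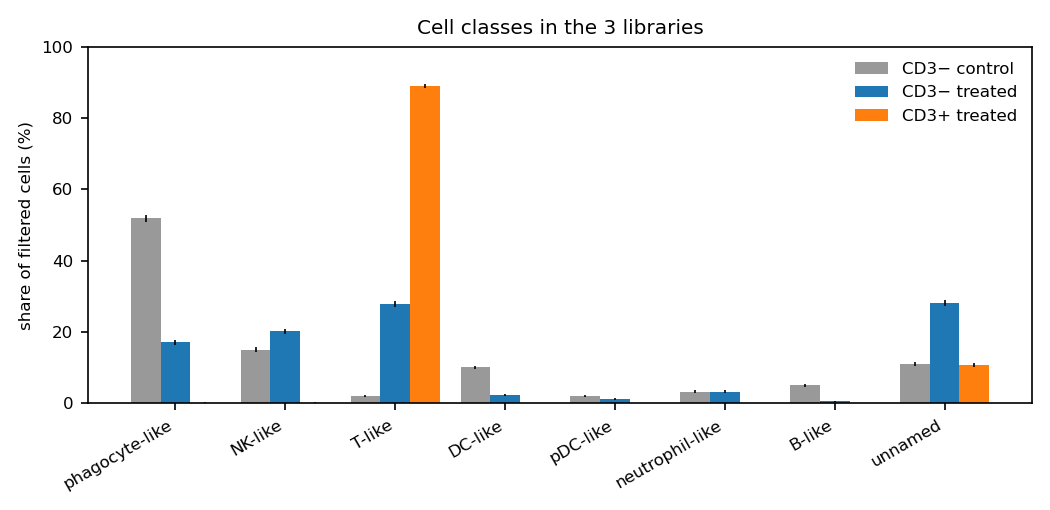
Share of filtered cells (vertical axis, percent) in each cell class for the 3 libraries, with exact 95% binomial intervals that cover counting error only. Phagocyte-like cells took 51.9% of the CD3− control and 17.1% of the CD3− treated library, and T-like cells took 89.1% of the CD3+ treated library.

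The second question was which genes differed within each class between treated and control CD3− libraries. In phagocyte-like cells the gene ranked highest was Wfdc21, a secreted whey acidic protein-domain gene, at 3.05 CPM in the control and 261 CPM in the treated library (log2 ratio 6.42, 6.13 to 6.72). Next came Lrg1 (9.35 and 559 CPM, log2 ratio 5.90) and Saa3, an acute-phase serum amyloid (14.3 and 724 CPM, 5.66), and the iron-binding lipocalin Lcn2 was also higher (3.86). Socs1, a feedback inhibitor of cytokine signalling, was 13.6-fold higher, at 21.9 and 299 CPM. S100a8 was higher too (58.0 and 1497 CPM, 4.69). Treated neutrophil-like cells held more of several of these genes, at 29210 CPM for S100a8, 1207 for Lcn2, 759 for Lrg1 and 520 for Wfdc21. The platelet factor 4 chemokine gene Pf4 was 172-fold lower, at 248 CPM in the control and 1.44 CPM in the treated library (log2 ratio −7.43, −7.98 to −6.92).

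The other genes named as lower in treated phagocyte-like cells were Cadm1 (log2 ratio −5.17), the tetraspanin Cd63 (308 and 15.7 CPM, −4.29), podoplanin gene Pdpn (−4.37), the chemokine gene Cxcl1 (−4.33), the matrix metalloproteinase Mmp13 (−4.06), the integrin Itga9 (66.1 and 4.13 CPM), Gdf15 (−3.94), the cyclin Ccnd1 (−3.87), the efferocytosis receptor Axl (−3.84), Ccl8 (−3.83) and Mtss1 (−3.75). The remaining genes ranked highest are lymphocyte genes. These were Cxcr6 (log2 ratio 4.89), Cd8b1 (4.54), Lag3 (4.12), Gzmb (12.7 and 202 CPM), Cd3d (3.95) and Cd3g (3.86). Cd8b1 reached 53.2 CPM in treated phagocyte-like cells against 1011 CPM in treated T-like cells, and all 8 measured T cell markers were higher (median log2 ratio 3.74). Phagocyte-like cells with no UMI of those markers numbered 5728 in the control and 892 in the treated library. Among them Cd8b1 was at 2.98, Cxcr6 at 3.23, Lag3 at 2.34, Gzmb at 3.52 and the cytotoxicity median at 2.26. Socs1 stayed at 3.77 and Wfdc21 at 6.56. The filter used T cell markers only, so RNA of NK-like cells, or T cell RNA without a marker UMI, could remain.

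The fixed gene lists separated the 2 interferon programmes in phagocyte-like cells. Of 14 measured interferon-γ response genes, 11 were at least 1.5-fold higher and 1 lower in the treated library, with a median log2 ratio of 0.83 (percentile 100 among random lists). Iigp1 was at 27.4 and 281 CPM and Irgm1 at 29.6 and 195 CPM, whereas Cxcl9 was lower, at 570 and 245 CPM. Of 12 type I interferon response genes, 0 were higher and 8 lower (median −0.79, percentile 0), with Rsad2 at 210 and 34.8 CPM and Isg15 at 1285 and 466 CPM. MHC class I genes were higher in 5 of 9 (median 0.63, percentile 98.2), led by H2-D1 at 948 and 2719 CPM. MHC class II genes were lower in 3 of 7 and higher in 1 (median −0.40, percentile 3.0), with H2-Ab1 at 2842 and 1206 CPM. Of 12 IL-10/STAT3 response genes, 6 were higher and 1 lower (median 0.66, percentile 99.7). Socs3 was at 106 and 503 CPM and Bcl3 at 58.6 and 210 CPM, while the interleukin-1 receptor antagonist Il1rn was lower, at 281 and 104 CPM.

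Genes of tumour macrophages, clearance and inflammation were lower in treated phagocyte-like cells. Of 12 measured tumour-associated macrophage genes, 0 were higher and 9 lower (median −2.38, percentile 0), among them Ms4a7 (183 and 14.5 CPM), Gpnmb (82.7 and 9.01 CPM) and arginase 1, Arg1 (206 and 37.1 CPM). Complement and phagocytosis genes were lower in 7 of 10 and higher in 0 (median −1.90, percentile 0), with C1qa at 754 and 103 CPM. Mrc1, Ms4a7 and Trem2 of the macrophage list and C1qa, C1qb, C1qc and Mertk of the complement list also named macrophage-like clusters. Treated cells lay mainly in a monocyte-like cluster, so these lists are not independent of the cluster names. Inflammatory cytokine genes were lower in 8 of 11 (median −1.15, percentile 0), with Cxcl2 at 4398 and 772 CPM, while Il1b was at 1154 and 1690 CPM. Chemokine genes were lower in 8 of 11 and higher in 2 (median −0.91, percentile 0), with Ccl7 at 1165 and 142 CPM and Ccl5 higher, at 205 and 715 CPM. DC maturation genes were lower in 7 of 13 (median −0.59, percentile 0.4).

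The remaining lists in phagocyte-like cells were cytotoxicity, with 11 of 12 genes higher (median 2.64, percentile 100), and T cell checkpoints, with 6 of 9 higher (median 2.16, percentile 100). Both hold genes that were at higher CPM in T-like or NK-like cells. Among cells with no T cell marker UMI the medians were 2.26 for cytotoxicity and 1.35 for checkpoints. Proliferation genes were lower in 5 of 12 and higher in 2 (median −0.41, percentile 2.4), and hypoxia and glycolysis genes lower in 5 of 11 (median −0.26, percentile 5.0). Medians were 0.01 for oxidative phosphorylation (percentile 32.1), 0.06 for dissociation stress (47.3), 0.30 for progenitor or memory T cell genes (77.3) and 0.16 for the IL-2/STAT5 response (62.4). The last was −0.22 among cells with no T cell marker UMI and −0.03 with each cell weighted equally. Cytokine receptor genes had a median of 0.88 (percentile 98.6), which was 0.23 among cells with no T cell marker UMI. Melanoma markers were lower in 5 of 5 measured genes (median −4.32), and fibroblast, endothelial and erythroid markers had fewer than 3 measured genes. Proliferation had a median of 0.05 with predicted doublets kept.

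NK-like cells of the treated library carried more granzyme RNA. Gzmd was at 2.51 CPM in the control and 865 CPM in the treated library (log2 ratio 8.43, 7.502 to 9.56). Gzme was at 0.558 and 404 CPM, with 2 control UMIs (log2 ratio 9.50, 7.65 to 12.55), and Gzmg at 0.279 and 261 CPM, with 1 control UMI (9.87, 7.39 to 15.17). These granzyme genes are close relatives on 1 chromosome, so the division of reads among them is uncertain. Of the 12 cytotoxicity genes, 9 were higher and 0 lower (median 1.62, percentile 100), including Gzmb (526 and 4352 CPM) and perforin, Prf1 (378 and 1253 CPM). Checkpoint genes were higher in 5 of 9 (median 1.73, percentile 100), with Lag3 at 10.6 and 164 CPM and Ctla4 at 39.1 and 354 CPM. T cell markers were higher too, in 6 of 8 (median 1.07). IL-2/STAT5 response genes were higher in 3 of 12 and lower in 3 (median −0.06, −0.153 to 0.057, percentile 56.4). Also named were the metallothionein Mt2 (log2 ratio 6.13) and the interferon-induced Ifitm1 (22.6 and 968 CPM, 5.42). Lower were the chemokine gene Ccl1 (82.3 and 2.24 CPM, −5.20), C1qa (−4.21), Cd83 (−3.96), Apoe (−3.84) and Abtb3 (460 and 43.0 CPM, −3.42). Control phagocyte-like cells held C1qa at 754 CPM and Apoe at 1167 CPM.

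The NK-like values depended on the cluster. Within cluster 9 (1335 control and 124 treated cells) the cytotoxicity median was −0.11, and within cluster 13 (448 and 615 cells) it was 1.91. The checkpoint medians were 1.29 and 1.13. T cell markers were higher in 5 of 7 and lower in 1 in cluster 9 (median 1.04), and higher in 7 of 7 in cluster 13 (median 2.005). Mki67, a marker of cycling cells, had a UMI in 1.46% of control and 3.84% of treated NK-like cells after thinning to 1000 UMIs, with 303 and 49 shallower cells left out, against 0.949% in treated phagocyte-like cells. Without thinning the NK-like shares were 2.82% and 12.3%, at median depths of 1749 and 3943.5 UMIs, beside 7.86% in treated phagocyte-like cells at 10066 UMIs. Proliferation genes were higher in 6 of 12 (median 0.52, percentile 98.9), and progenitor or memory genes lower in 7 of 10 (median −1.08, percentile 0), but the memory median was 0.023 within cluster 9 and −0.404 within cluster 13. Proliferation genes were higher in 2 of 7 within cluster 9 (percentile 76.6) and 3 of 8 within cluster 13 (percentile 50.9).

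Neutrophil-like cells, which all lay in cluster 16, had the highest interferon-γ median of the compared classes. Of 14 measured genes, 11 were higher and 1 lower (median 1.76, percentile 100), with Socs1 at 17.4 and 449 CPM (log2 ratio 4.69), Irgm1 at 31.5 and 333 CPM and inducible nitric oxide synthase, Nos2, at 7.60 and 62.4 CPM. MHC class I genes were higher in 7 of 9 (median 1.18), and inflammatory cytokine genes in 5 of 9 (median 1.37), with Tnf at 90.1 and 429 CPM and Il1b at 2043 and 7425 CPM. Tgtp1 (5.00), Thy1 (4.34), Saa3 (4.30) and Gzmb (4.04) were also named as higher. Thy1 stood at 1122 CPM in treated T-like cells and Gzmb at 4352 CPM in treated NK-like cells. T cell markers were higher in 6 of 7 (median 2.61) and cytotoxicity genes in 11 of 12 (median 2.646). Lower were the antimicrobial peptide gene Camp (330 and 6.86 CPM, −5.59), the scavenger receptor Cd36 (−5.37), Hspa1b (−3.83), Hspa1a (−3.46) and Apoe (−3.03). Control phagocyte-like cells held Apoe at 1167, Hspa1a at 303, Hspa1b at 144, Cd36 at 133.5 and Camp at 0 CPM. Complement and phagocytosis genes were lower in 7 of 8 and higher in 1 (median −1.75, percentile 0). Type I interferon genes were split, with 3 of 11 higher and 2 lower (percentile 69.3). At resolution 2.0 a cluster of 109 control and 59 treated cells stayed unnamed. It scored 0.93 for neutrophil and 0.773 for non-classical monocyte markers, at a median of 5903.5 UMIs. The named neutrophil-like cluster there had 1645.5. Expression was not recomputed at that resolution, so such mixed cells may contribute to the differences above.

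DC-like cells also had a higher interferon-γ list, with 8 of 13 genes higher (median 1.19, percentile 100), and a higher IL-10/STAT3 list, with 7 of 12 higher (median 0.81, percentile 99.7). Socs3 was at 38.9 and 370 CPM. Dissociation stress genes were higher as well, in 5 of 8 (median 1.01, percentile 99.8; 0.988 within cluster 11). DC maturation genes were lower in 9 of 13 and higher in 0 (median −0.96, percentile 0). Il12b, which encodes a subunit of interleukin 12, was at 160 and 3.87 CPM (log2 ratio −5.37) and Ccl22 at 151 and 7.09 CPM (−4.42). Ccl17 was at 108 and 0.966 CPM, with 3 treated UMIs (−6.80, −9.08 to −5.25), Tnfrsf4 was lower (−5.01), and Hspb1 had 152 control UMIs (20.9 CPM) and 0 treated UMIs. The migratory Ccr7+ cluster 22 held 321 control and 10 treated cells. Ccr7, Fscn1 and Ccl22 of the maturation list were also markers that named this cluster. The maturation list is therefore not independent of the make-up of the class. Within cluster 11 (884 and 254 cells) the maturation median was −0.52, the interferon-γ median 1.18 and the chemokine median 0.07, against −1.14 for chemokines in the whole class. Genes named as higher were Lrg1 (5.37), Cxcr6 (5.14), Prtn3 (4.47), Cd3d (4.27) and Cd8b1 (4.17), beside T cell markers higher in 8 of 8 (median 3.50).

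In pDC-like cells, 6 of 8 type I interferon genes were lower and 0 higher (median −1.13, percentile 0), while MHC class II genes had a median of 0.45 (percentile 94.9). Il31ra was at 666 and 73.1 CPM (log2 ratio −3.19), Cxcl9 at −4.04, Pgam2 at −2.87, Cdk8 at −2.80, and Hspa1b had 1 treated UMI (−5.56, −10.89 to −3.02). Control phagocyte-like cells held Il31ra at 693.5, Cxcl9 at 570, Cdk8 at 2936 and Hspa1b at 144 CPM. Pgam2 reached only 0.275 CPM in control DC-like cells, its highest other class. Complement and phagocytosis genes were lower in 4 of 6 and higher in 0 (median −1.98). The genes named as higher were Cd3d (5.24), Gzmb (4.01), Ccl5 (3.25), Ms4a4b (3.25) and Nkg7 (3.10), all of which were at higher CPM in T-like or NK-like cells. T cell markers were higher in 5 of 6 (median 3.56).

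T-like cells of the CD3− libraries numbered 236 in the control and 3429 in the treated library. Ifitm1 was at 14.5 and 1848 CPM (log2 ratio 6.998, 6.19 to 7.95). Granzymes Gzmb (235 and 2990 CPM, 3.67), Gzmk (3.66) and Gzma (3.30), and Ifitm2 (3.19), were higher as well, and 11 of 12 cytotoxicity genes were higher (median 1.60, percentile 100). Type I interferon genes were higher in 7 of 11 (median 0.99, percentile 100), opposite in sign to phagocyte-like cells. Ccr7, a receptor for lymph node homing, was at 108 and 0.931 CPM (−6.86), with Dapl1 (−6.12), Cd83 (−4.79), Tnfsf4 (−4.74) and Dscam (−4.54) also lower. C1qa was at 55.4 and 5.89 CPM in these cells. The contrast mixes clusters. At resolution 2.0 a T-like cluster led by Pkp4, Dscam and St6galnac3 held 153 control and 8 treated cells. Within cluster 0 at resolution 1.0 (108 and 2083 cells) the cytotoxicity median was 1.70 and the type I interferon median 1.10. Whether cells of that smaller cluster lay in cluster 0 was not examined. The TMM scaling factor shifted all log2 ratios by 0.23 in NK-like, 0.26 in T-like, −0.19 in DC-like, −0.13 in pDC-like and 0.15 in neutrophil-like cells, and centring on the median gene made DC-like ratios lower by 0.16 and neutrophil-like ratios higher by 0.115.

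The third question was what the CD3+ sort of treated tumours contained. T-like cells were 89.1% of the library (88.5 to 89.7; 9338 of 10481 cells), and unnamed clusters 10.6%, mainly cluster 7 (426 cells), cluster 15 (377 cells) and cluster 19 (282 cells). Phagocyte-like and NK-like cells were 11 cells each, neutrophil-like cells 7 and DC-like cells 4. Of the T-like cells, 83.6% had a UMI of Cd8a, 4.18% of Cd4 and 0.418% of Foxp3, the regulatory T cell factor, and after thinning the shares were 45.8%, 1.31% and 0.184%, with 117 shallower cells left out. Only 39 cells had a Foxp3 UMI, fewer than the 100 cells set as the minimum, so the planned contrast of CD8 and regulatory T cells was not made. Clusters 0 (43.9% of T-like cells), 3 (19.01%), 2 (18.0%) and 10 (11.9%) held most of them, and clusters 3 and 21 (2.87%) were cycling.

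These CD3+ T-like cells held effector RNA. Gzmb was at 3021 CPM (3006 to 3036), Gzma at 1583 CPM, Ifng at 466 CPM and Prf1 at 553 CPM. Checkpoint genes stood at 628 CPM for Pdcd1, 501 CPM for Ctla4 and 429 CPM for Lag3. The progenitor factor Tcf7 was at 23.4 CPM. Mki67 had a UMI in 16.2% of them after thinning (36.7% before).

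T-like cells of the treated CD3+ and CD3− sorts were then compared, a contrast chosen after T-like cells were seen in the CD3− library. The contrast mixes clusters: cycling cluster 3 held 19.01% of CD3+ and 10.1% of CD3− T-like cells, cluster 10, led by Tnfsf11, Tnfrsf4 and Phlda1 among others, 11.9% and 3.15%, and cluster 0 43.9% and 60.7%. No comparison within those clusters was made. T cell markers were near equal in level, with a median log2 ratio of −0.02 (CD3+ over CD3−) and 0 of 8 markers differing by 1.5-fold. The T-like clusters were named from these markers, so their near-equal level follows partly from the naming. Cd3e was at 852 and 866 CPM. The CD3+ cells had higher proliferation genes in 6 of 12 (median 0.57, percentile 100) and higher IL-2/STAT5 response genes in 5 of 12 (median 0.57, percentile 100), with Il2ra at 199 against 109 CPM and Pim1 at 443 against 291 CPM. Cytotoxicity genes were lower in 3 of 12 (median −0.30, percentile 0), with Ccl5 at 3651 against 7944 CPM and Gzma at 1583 against 3044 CPM. Treated NK-like cells of the CD3− library held Gzma at 18060, Ccl5 at 10920 and Klrb1b at 402 CPM. NK cell markers stood in CD3− T-like cells at 10.37% of their level in NK-like cells. How much of these differences came from NK-like RNA was not tested. By rank, Tnfsf11 (69.6 against 14.7 CPM, log2 ratio 2.24), Tnfrsf4 (1.74), H3c2 (1.47), Phlda1 (1.29) and Ttc39c (1.25) were higher in CD3+ cells. Lower were Klrb1b (−3.99) and the myeloid genes Chil3 (−5.41), S100a8 (−5.27), S100a9 (−4.86) and Il1b (−4.61), and MHC class II genes had a median of −2.85. Chil3 stood at 2901 CPM and S100a8 at 29210 CPM in phagocyte-like and neutrophil-like cells of the CD3− treated library.

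The last comparison placed the receptors of the injected cytokines. Il10ra, the ligand-binding chain of the IL-10 receptor, was highest in neutrophil-like cells (301 CPM in the control and 185 CPM in the treated library) and phagocyte-like cells (244 and 209 CPM), then DC-like cells (179 and 175 CPM), and was at 62.4 CPM in CD3+ T-like cells. Il10rb was at 67.5 and 72.9 CPM in phagocyte-like cells. Il2rb, the signalling β chain of the IL-2 receptor, was at 1166 and 978 CPM in NK-like cells, 625 and 639 CPM in T-like cells and 624 CPM in CD3+ T-like cells. Il2rg was at 259 and 495 CPM in NK-like cells and 530 CPM in CD3+ T-like cells. Il2ra, the α chain of the IL-2 receptor, was at 199 CPM (196 to 203) in CD3+ T-like cells and 68.7 and 62.9 CPM in NK-like cells. It was at 104 and 109 CPM in T-like cells of the CD3− libraries, and 29.9 and 9.66 CPM in DC-like cells. After thinning, Il2ra had a UMI in 18.0% of CD3+ T-like cells and 10.3% of T-like cells in the treated CD3− library (48.5% and 27.9% before, 117 and 74 shallower cells left out). Treated phagocyte-like cells gave 0.475% (4.45% before, 6 left out), at median depths of 10066 UMIs against 4622 and 4001.

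**Figure D2:**
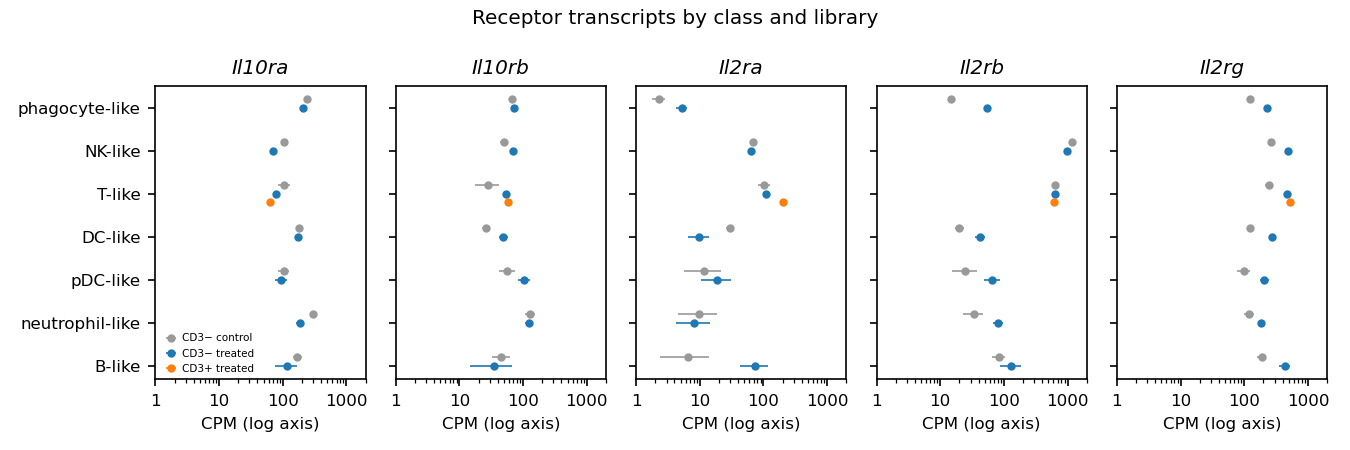
CPM of the 5 receptor genes (log axis) by cell class and library, with exact 95% Poisson intervals that cover counting error only, for classes with at least 50 cells. Il10ra lay highest in neutrophil-like and phagocyte-like cells, and Il2ra in CD3+ T-like cells at 199 CPM.

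Cd3e is among the markers that named T-like cells, so its share in them does not check the sort. It had a UMI in 50.04% of CD3+ T-like cells and 49.4% of T-like cells in the treated CD3− library after thinning (85.7% and 78.2% before). NK-like cells of the treated CD3− library gave 5.28% (15.9% before) and phagocyte-like cells 3.56% (20.4% before). In genome build GRCm38 the protein-coding genes that led these comparisons lie on chromosome 11 at 83746940 to 83752642 (Wfdc21), chromosome 16 at 10782240 to 10785536 (Socs1), chromosome 5 at 90772435 to 90773383 (Pf4), chromosome 14 at 56117626 to 56120625 (Gzme) and 56129556 to 56132608 (Gzmd), chromosome 7 at 140967221 to 140969825 (Ifitm1), and chromosome 14 at 78277445 to 78308043 (Tnfsf11). Counts were per gene, so no exon or untranslated region is singled out.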

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

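Each group had 1 library, so no result has a replicate spread, and alternatives were compared with the counting interval of the value in the report. No paired analysis was possible because each group had 1 library. The naming versions, non-T shares, cells without T cell marker UMIs, and comparisons within clusters were chosen after seeing the data. Every share ratio kept its direction except that of neutrophil-like cells, which lay near 1. The comparison of T-like cells between sorts was not repeated under the alternatives, and own clustering gave no DC-like class in the treated library. The cause of each difference below was not tested. Depth limits classes of few cells, and thinned shares moved with the depth chosen. The mitochondrial limits of 5% and 20% moved no share ratio.

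For shares, 500 detected genes gave 90.86% T-like cells in the CD3+ library and a neutrophil-like ratio of 1.161. Resolution 0.5 gave an NK-like ratio of 2.441, and resolution 2.0 gave 0.3499 (phagocyte-like), 1.273 (NK-like) and 1.182 (neutrophil-like). Clustering on marker genes gave 91.83% T-like cells in the CD3+ library and ratios of 0.3438 (phagocyte-like), 2.529 (NK-like), 7.256 (T-like), 0.1708 (DC-like) and 0.8472 (neutrophil-like). Clustering each library on its own gave 0.4115 (phagocyte-like) and 6.269 (T-like). Keeping doublets gave 0.3657 (phagocyte-like). Marker scores from CPM and a rival limit of 0.8 each gave an NK-like ratio of 2.167 and an NK-like cytotoxicity median of 1.226. Over non-T cells the ratios were 0.447 (phagocyte-like), 1.829 (NK-like), 0.2903 (DC-like), 0.7963 (pDC-like), 1.356 (neutrophil-like) and 0.1288 (B-like).

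For list medians in phagocyte-like cells, clustering on marker genes gave interferon-γ 0.6977, MHC class I 0.5456, checkpoints 1.621, T cell markers 2.593, chemokines −0.7583, complement −2.117, receptors 0.7601, dissociation stress 0.101, inflammatory cytokines −1.08, DC maturation −0.5295 and proliferation −0.7055. Per-cell means gave interferon-γ 0.7467, IL-10/STAT3 0.5466, MHC class II −0.2971, checkpoints 1.712, T cell markers 3.31, complement −1.623, receptors 0.7815, cytotoxicity 2.284, hypoxia −0.3838, inflammatory cytokines −1.116, DC maturation −0.6281, oxidative phosphorylation 0.04658, memory genes 0.111, proliferation −0.1364 and tumour-associated macrophage genes −2.56, and turned IL-2/STAT5 (−0.03409) and dissociation stress (−0.06349). Keeping doublets gave interferon-γ 0.7593, IL-2/STAT5 0.4162, MHC class II −0.4906, chemokines −1.019, complement −2.028, receptors 0.9935, cytotoxicity 3.524, dissociation stress 0.007835, inflammatory cytokines −1.027 and DC maturation −0.6758, and turned proliferation (0.0542). Cells without T cell marker UMIs gave MHC class II −0.4659, checkpoints 1.353, chemokines −1.056, complement −2.284, receptors 0.2257, cytotoxicity 2.264, hypoxia −0.3452, inflammatory cytokines −1.202, melanoma markers −3.073, memory genes 0.0904 and tumour-associated macrophage genes −3.084, and turned IL-2/STAT5 (−0.2218). Centring on the median gene gave IL-10/STAT3 0.6074, MHC class I 0.5689, MHC class II −0.4548, chemokines −0.9711, complement −1.957, dissociation stress 0.003628, inflammatory cytokines −1.209, DC maturation −0.6427 and oxidative phosphorylation −0.04693. With no minimum count, complement was −2.122 and tumour-associated macrophage genes −2.474.

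In NK-like cells, the main medians were IL-2/STAT5 −0.06, interferon-γ −0.383, IL-10/STAT3 −0.553 and dissociation stress −0.562. For these cells, TMM gave IL-2/STAT5 0.1732 and cytotoxicity 1.85, and marker clustering 0.2315 and 1.294. Per-cell means gave 0.2213 and 1.418, cluster 13 alone 0.2049 and 1.912, and centring gave cytotoxicity 1.689. Cluster 13 turned interferon-γ (0.1667). Cluster 9 gave IL-2/STAT5 −0.533 and turned cytotoxicity (−0.1103), IL-10/STAT3 (0.3409), interferon-γ (0.1277), dissociation stress (0.501) and memory genes (0.02281). In DC-like cells, maturation was −0.7519 with marker clustering, −1.219 with per-cell means and −0.519 in cluster 11. MHC class II turned with TMM (−0.16), centring (−0.1305) and cluster 11 (−0.1114), chemokines turned in cluster 11 (0.06519), and IL-2/STAT5 turned with no minimum (−0.02061). In T-like cells, TMM turned dissociation stress (0.008288) and oxidative phosphorylation (0.07649), per-cell means turned the latter (0.07851), and cluster 0 turned tumour-associated macrophage genes (0.1644). Keeping doublets gave neutrophil-like interferon-γ 1.404 and turned pDC-like hypoxia (−0.5445) and inflammatory cytokines (0.108), and no minimum turned pDC-like hypoxia (−0.5151).

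Shares with an Il2ra UMI in NK-like treated, NK-like control, CD3− treated T-like and CD3+ T-like cells were 15.84, 6.475, 27.91 and 48.5% without thinning and 8.376, 8.131, 16.24 and 29.3% at 2000 UMIs. Mki67 gave 12.27, 2.822, 21.76 and 36.68%, and 6.832, 2.425, 14.87 and 24.82%. Of the named genes and most lists outside phagocyte-like cells, 129 stayed within their interval with TMM, 36 moved and 3 turned. With marker clustering 101 stayed and 68 moved, and with doublets kept 132 stayed, 35 moved and 2 turned. The counts for marker clustering and doublets also hold the unnamed share of the CD3+ library.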

Other observations

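All 7 tests in this part, and Spp1 and the clusters described, were chosen after the results were seen. Spp1, which encodes the secreted phosphoprotein osteopontin, was lower in treated phagocyte-like cells (567 and 186 CPM) and higher in treated NK-like cells, at 28.2 CPM in the control and 1161 CPM in the treated library (log2 ratio 5.36). It was also higher in neutrophil-like cells (160 and 608 CPM) and T-like cells of the CD3− sort (37.3 and 144 CPM), and stood at 66.9 CPM in CD3+ T-like cells. Cdk8 was at 2936 CPM in control and 608 CPM in treated phagocyte-like cells, beside the pDC-like values in the report.

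The unnamed clusters held lymphoid and myeloid cells. Cluster 8 (23 control and 1567 treated cells) was led by Gzmc, Xcl1 and Klrb1b, with an NK cell score of 0.482 and a monocyte score of 0.375. Monocyte scores were 0.35, 0.198 and 0.158 in NK-like clusters 6, 13 and 9, and 0.382 in T-like cluster 10. That score alone therefore does not mark cluster 8 as monocyte-like. Cluster 7 (240 and 958 cells) was led by Klra1, Klra7 and Klra6, with a T cell score of 0.585 and an NK cell score of 0.482. Its cytotoxicity median was 1.35 and its checkpoint median 1.49. Cluster 12 (858 and 261 cells) had a macrophage score of 0.429 and higher interferon-γ genes in the treated library (median 0.97). T cell markers were higher there in 7 of 7 (median 3.06), cytotoxicity genes in 10 of 11 (3.09) and checkpoint genes in 7 of 9 (2.44). Its tumour-associated macrophage median was −2.34. Cluster 19, with a median of 651 UMIs per cell, was led by haemoglobin genes, but all 4225 haemoglobin UMIs of its 517 cells lay in 1 control cell.

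T-like cells in the treated CD3− library were examined for technical sources. Barcodes shared with the CD3+ library made up 1.604% of them and 1.802% of other barcodes, which does not support carry-over. Their Cd3e level was 101.7% of that in CD3+ T-like cells, while 6 other classes of the same library stood at 4.76 to 8.72% of it. Cd3e is among the markers that named T-like cells, so the naming partly sets this gap. The comparison therefore does not decide on free RNA. Markers of those 6 classes stood in the T-like cells at 18.07% of their own-class level, summed over classes. Most of this came from NK-like (10.37%) and phagocyte-like (6.278%) markers, with 0.168% from neutrophil-like ones. Whether T-like cells express those markers themselves was not tested. The sum lies below the 34.19% that a neutrophil-like cell of median depth, the shallowest class, would bring to a doublet. A mean over cells cannot count doublets, which do not account for all of the T-like cells but stay open for a part. Low surface CD3 and escape from the sort also stay open.

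T and NK cell transcripts in treated phagocyte-like cells were tested against RNA from T-like cells. The 8 T cell markers stood at 3.05% (Themis) to 6.74% (Trbc2) of their T-like level, a ratio of 2.213 with a counting interval of 1.96 to 2.499 that includes the limit of 2 set for the test. This test cannot tell whether 1 source of RNA could account for them. Cd3e had a UMI in 20.44% of the cells against 37.76% for evenly spread counts, 54.14% of that share, which speaks against evenly spread free RNA alone. Doublets, attached cells and uptake were not told apart.

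Lower macrophage and complement genes in treated phagocyte-like cells were tested against dilution and scaling. RNA of T-like cells was estimated at 5.3% of UMIs, whereas C1qa, C1qb and C1qc were lower by 86.3, 68.8 and 77.0%, so dilution is unlikely to account for the difference. The list median nearest 0 under either scaling was −1.916. At resolution 1.0 the control cells lay mainly in macrophage-like clusters and the treated cells mainly in a monocyte-like cluster. At resolution 2.0 the largest control clusters were named monocyte-like as well. Whether cells were replaced or altered was not tested.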
